A study of Mus musculus with 2 samples.

How the data were processed

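RNA was measured in superficial zone (SFZ) cells of mouse articular cartilage, the thin layer of flattened chondrocytes that faces the joint space. The cells came from C57BL/6 mice at postnatal day 5. The 2 libraries were 1 from wild-type (WT) mice and 1 from mice lacking Prg4 (Prg4KO), the gene for lubricin, the secreted proteoglycan that lubricates the joint surface. Per the labels' protocols, cartilage from the femur and the upper tibia was freed of ligament, tendon and synovium and treated with 0.25% trypsin for 1 hour and with type I collagenase at 173 U/mL for 1.5 hours. The released cells were plated on fibronectin, and polyadenylated RNA was sequenced. The number and sex of the mice per library and the time in culture are not given in the sources used here.

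Per the file headers, the deposited values for each library were expected counts and FPKM. An expected count is an estimate of the reads from a gene and need not be whole where genes share reads. FPKM, as deposited by the authors, is the count scaled by effective transcript length and library size. The submitters' processing notes name HISAT2, Bowtie2, RSEM and the mouse build mm10, without versions or roles. Strand use, read length and counting options are not given in the sources used here, so reads shared between near-identical or overlapping genes may have been split between them. The values carried 2 decimals, and genes at 0 were not listed (0 listed values were 0 in either library). Expected counts summed to 21619093 in the WT library and 21392574 in the Prg4KO library, which was 98.4% and 98.3% of the library sizes implied by count and FPKM together.

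The deposited Prg4KO values did not stand beside the gene they belong to. The table named 15719 genes with WT values and held 15973 pairs of Prg4KO values, 254 of them beside no gene. Across genes, log2 FPKM correlated between libraries at r = 0.96 over the first 20 rows and at r = 0.0841 over the later ones. The Prg4KO values were therefore re-paired with the genes, a step devised after the data had been examined, and every Prg4KO value given for a gene rests on it. Count divided by FPKM gives the effective length of a gene up to a constant for the library, here the deposited length in bases minus 36.5. The WT genes were sorted by gene number as text, and both libraries were taken as ordered subsets of that gene list with genes at 0 left out. A pair hidden Markov model with 3 states (both libraries, WT only, Prg4KO only) and the forward-backward algorithm gave the probability of each pair from order and effective length. A gene could be missing from the other library with a base probability of 0.002 plus 0.4 near a count of 0, falling by a factor e per 3 counts. An exact length match, to rounding and 0.02%, had a weight of 97% for genes with 1 transcript and 30% for the 5963 genes with several. Other shifts of log length followed narrow (0.02) and wide (0.2) Laplace distributions. The levels of the 2 members of a pair were not compared, but the count of a row did set how likely it was to lack a partner.

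Pairs at a probability of 0.95 or more were used, which covered 15037 genes (95.7%), including 6840 of the 6840 genes with a WT FPKM of at least 5. Their log2 FPKM correlated at r = 0.981 across genes, which are not independent replicates. Over 1709 of these genes with 1 transcript and a WT FPKM above 20, the effective lengths of a pair differed by a median of 0.0039%. This was the second version of the model. In the first, every row was equally likely to lack a partner and length shifts had a single distribution, and Tsc22d3 (1570 WT counts) was paired with a Prg4KO row of 1 count. That ratio was noticed because it was extreme, and the model was then revised. The second version pairs Tsc22d3 with a row of 1922 counts at a probability of 0.954, and it raises the probability for Rps27a from 0.852 to 1.00. Of 14813 genes paired at that limit by both versions, 1 had another row in the first, and this was Tsc22d3. All results use the second version.

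The pairing and the limits of size were tested on simulated data for the Prg4KO against WT comparison. In each of 3 runs over the 15719 genes, Prg4KO counts were drawn from the WT counts with 200 genes changed, transcript mixes shifted and 500 rows without a WT partner added. At a probability of 0.95, 0 of 20459 pairs with a WT FPKM of at least 5 were wrong, and 10 of 45344 pairs overall. The limits were passed by 99.3% of genes simulated at 0.25-fold, 87.3% at 0.4-fold, 96.7% at 2.5-fold and 100.0% at 4-fold. They were also passed by 43 of 20144 unchanged genes (0.213%). Apart from the changes set, the simulated counts varied by counting error alone. They had no spread between cultures, no trend with transcript length and GC content and no shift in the all-gene median. The shares passing the limits therefore need not hold for the 2 measured libraries. No change as large as that of Prg4 was simulated.

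With 1 library per genotype, no test of genotype was possible. The choices in the next sentences were made before the data were examined. The log2 ratio of a gene is log2((Prg4KO FPKM + 1)/(WT FPKM + 1)), which understates the ratio of genes with low values. A gene counted as higher or lower in the Prg4KO library when its larger FPKM was at least 5 and its log2 ratio at least 1 or at most -1. Named genes are Prg4, the 12 largest and 12 smallest log2 ratios past both limits with clone and model names left out, and, per gene list, up to 4 members past the limits or else the 2 with the highest mean FPKM. Mmp9, Tgfb1, Nfkb1, Rela, Cd44, Tlr2, Tlr4, Col2a1, Acan, Sox9 and Col10a1 are named whatever their values. Other genes given as examples of a list were chosen after their values were seen. For 40 gene lists of pathways and cell types, the median log2 ratio was taken over members whose larger FPKM was at least 1, where there were 5 or more, which held for 34 lists. Lists overlap, and the number of measured members also in another list was 6 for hypertrophic and osteoblast, 4 for tendon and ligament, 3 for matrix proteases, 2 for osteoclast, YAP, hypoxia and housekeeping, and 1 for NF-kB, both TGF-beta lists, fibrous matrix, superficial zone, chondrocyte matrix, immediate early, mural, skeletal muscle and the chromosomal neighbours of Prg4. Each median was placed among the medians of 10000 random lists of the same size matched in 20 bins of mean expression. These percentiles describe the 2 libraries and are no test.

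Counts carry exact Poisson 95% intervals, and ratios of counts per library total carry exact conditional binomial (Clopper-Pearson) ones, with expected counts rounded to whole numbers first. Medians of lists carry binomial order-statistic intervals over their members. All intervals on counts cover counting error only, since sequenced copies are not independent molecules and no replicate measures the spread between cultures. Coordinates are those of GRCm38 (mm10) in the RefSeq gene table, where 15705 of the gene numbers were found. Symbols that had been turned into dates were restored by gene number for 25 genes.

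The alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, rescaling to a common sum, median or upper quartile, rescaling without the 20 most abundant genes, TMM factors on the deposited expected counts (edgeR, prior count 1), other limits on FPKM and on the log2 ratio, and means in place of medians. Alternatives chosen after seeing the data were pairing probabilities of 0.5 and 0.99, pairs whose neighbours on both sides show the same shift of rows, the first pairing model, and removal of a trend with transcript length and GC content. That trend was fitted over 6691 genes, with GC content from GENCODE vM21 transcripts known for 99.7% of the paired genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, R 4.3.3 and edgeR 4.0.16 were used.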

Results

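Gene expression was compared between superficial zone cells of articular cartilage from wild-type mice and from mice without Prg4, to ask what the loss of lubricin does to the transcripts of the cells that make it. Each genotype had 1 library, so no difference below has a replicate check, and each describes these 2 libraries. The totals were 21619093 expected counts in the WT library and 21392574 in the Prg4KO library. FPKM was at least 1 for 10772 genes in the WT library and for 11057 in the Prg4KO library. All Prg4KO values per gene rest on the re-pairing of the deposited values with gene names. Col2a1, the main cartilage collagen, had the highest FPKM in both libraries, at 14594 in the WT library and 15702 in the Prg4KO library.

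**Figure D1:**
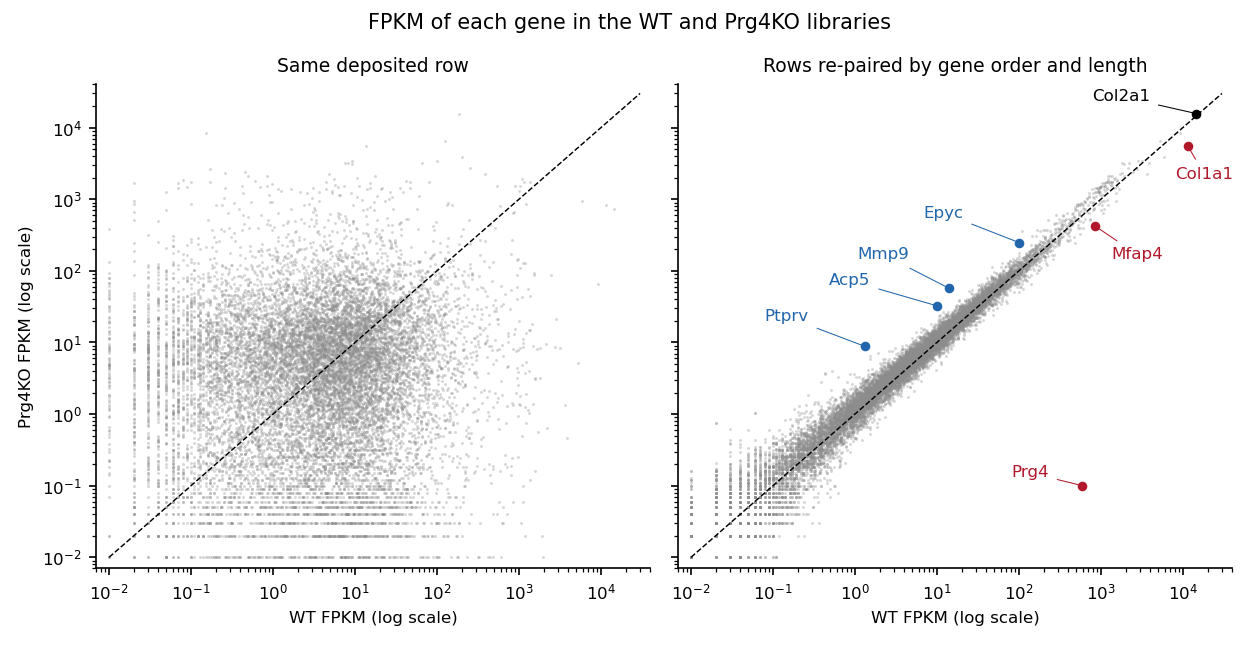
FPKM of each gene in the WT library (horizontal, log scale) and in the Prg4KO library (vertical, log scale), with each point a gene and the dashed line marking equal values. On the left the values stand as in the deposited rows (r = 0.0851 across genes on the log2 scale), and on the right after re-pairing (r = 0.981), where Prg4 lies far below the line at 593 and 0.10 FPKM.

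Prg4 itself was nearly absent from the Prg4KO library. The gene (gene number 96875, chromosome 1 from 150449412 to 150466221 in GRCm38) ranked 119 by FPKM among WT genes, with 54559 expected counts (95% Poisson interval 54102 to 55019) and an FPKM of 593. In the Prg4KO library it had 6.15 counts (2.2 to 13.1) and an FPKM of 0.10, which is a log2 ratio of -9.08. Per library total, the Prg4KO count was 0.0111% of the WT count (0.00408% to 0.0242%, counting error only). The probability of this pair was 0.998, and the neighbouring pairs on both sides showed the same shift of rows. At so few counts the effective length differed by -32.6% from that in the WT library, so the pair rests on gene order more than on length. Its probability also rests on the base probability of 0.002 for a missing partner, which need not hold for the knocked-out gene. If Prg4 was at 0 and unlisted in the Prg4KO library, the 6.15 counts would belong to another gene.

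Beyond Prg4, few genes differed by a factor of 2 or more. Of 7367 genes with a larger FPKM of at least 5, 34 were higher and 8 were lower in the Prg4KO library, Prg4 included. The genes with the largest log2 ratios, at a pseudocount of 1, were Ptprv, a receptor-type tyrosine phosphatase found in bone-forming cells, and Mmp9, the gelatinase secreted by osteoclasts and inflammatory cells. Ptprv had 175 counts in the WT library and 1161 in the Prg4KO library (ratio per library total 6.70, 5.71 to 7.91), at FPKM 1.32 and 8.82. Mmp9 had 979 and 3908 counts (ratio 4.03, 3.76 to 4.33), at FPKM 14.1 and 56.9. Acp5, which encodes the tartrate-resistant acid phosphatase of osteoclasts, had 303 and 944 counts (ratio 3.15, 2.76 to 3.60), at FPKM 10.2 and 32.3.

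Several cartilage genes were among the higher ones. Epyc, a small leucine-rich proteoglycan of cartilage, had an FPKM of 101 in the WT library and 247 in the Prg4KO library (log2 ratio 1.28). Panx3, a pannexin channel of prehypertrophic chondrocytes and osteoblasts, had 47.4 and 112 (1.23), and Matn3, a cartilage matrilin, had 168 and 377 (1.16). Spp1, which encodes osteopontin, had 142 and 304 (1.09). Foxa2, a transcription factor of hypertrophic chondrocytes, had 6.35 and 16.1 (1.22), and Elf3, an epithelial and inflammatory transcription factor, had 1.51 and 5.81 (1.44). The remaining named genes on this side were Erdr1 (108 and 365 FPKM), Fabp7 (1.51 and 6.46), Wdfy1 (1.89 and 7.02), the Y-linked Eif2s3y (2.60 and 7.49) and Polr2k (3.04 and 8.47). Wdfy1 had expected counts that were not whole, which points to reads shared with other genes, and its effective length differed by 15.8% between the libraries.

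The lower genes other than Prg4 included Col1a1 and Mfap4, which encode connective tissue matrix. Col1a1, the main chain of type I collagen, had an FPKM of 11470 in the WT library and 5593 in the Prg4KO library, from 1488747 and 719573 counts (ratio 0.489, 0.487 to 0.490), and its log2 ratio of -1.04 was -0.71 after removal of a trend with transcript length and GC content, inside the limit. Mfap4, a microfibril-associated protein, had 848 and 423, and Ssc5d, a secreted scavenger receptor protein, had 140 and 65.7 (log2 ratio -1.08). Cryab, a small heat shock protein, had 71.9 and 35.4, Coro2b 9.83 and 4.13 (-1.08), Cited1 11.3 and 5.05 (-1.02), and Ptx4 5.32 and 2.08 (-1.04). Neighbouring pairs on both sides were in the same register for 34 of the 42 genes past the limits. They were not for Mmp9, Ssc5d, Coro2b, Steap1, Rps27a, Chil1, Nhej1 and a gene model, and the effective length of Mmp9 differed by 0.005% between the libraries.

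The split between higher and lower genes depended on the scaling. The median log2 ratio of 6699 genes with FPKM of at least 5 in both libraries was 0.13, and Col1a1, Col1a2 and Col3a1 took 10.5% of WT counts against 5.9% of Prg4KO counts. As deposited, 81.0% of genes past the limits were higher, against 53.7% after rescaling to a common sum, 48.5% to a common median, 58.1% to a common upper quartile, 46.3% without the 20 most abundant genes and 51.0% with TMM factors. List medians below are given relative to the all-gene median. Log2 ratios also went with transcript properties (Spearman's rho across genes -0.31 with length and -0.35 with GC content), and a trend in both held 26.6% of their variance. Genes with small ratios turn sign with these choices: Col2a1, Nfkb1, Tlr4, Cyr61, Atf4, Id3, Phlda3, Fdps, Des and Tgfbi under several rescalings, Sox9, Id1, Pcna and Ube2c without the 20 most abundant genes, and Acan, Tgfb1, Cebpa and Cspg4 after removal of the trend. Of the 42 genes, 21 were still past the limits after its removal, and 24 after rescaling to a common median. Of the named genes, Epyc, Eif2s3y, Polr2k, Spp1, Rps27a, Rpl22l1, Col1a1, Ssc5d and Coro2b no longer passed after the trend was removed, and Spp1, Rps27a and Rpl22l1 no longer passed at a common median.

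Genes of fibrous connective tissue were lower as a group in the Prg4KO library. Of the 20 members of the fibrous matrix list, 19 lay below the all-gene median, and the list median was -0.75 (95% interval over members -0.84 to -0.52), below all 10000 matched random lists (percentile 0.0). Beside Col1a1, its partner chain Col1a2 had an FPKM of 5838 in the WT library and 3869 in the Prg4KO library (log2 ratio -0.59). The type VI collagen gene Col6a2 had 1536 and 937 (-0.71), elastin (Eln) 123 and 74.4 (-0.72), and tenascin X (Tnxb) 11.1 and 5.27 (-0.95). The exception was lumican (Lum), a collagen-binding proteoglycan, with 168 and 222 (0.41). The list median was -0.52 relative to all genes after the length and GC trend was removed (percentile 0.0).

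Genes that mark the superficial zone also lay below the all-gene median as a group, with or without the knocked-out gene. The list of 23 genes had a median of -0.45 relative to all genes (-0.52 to -0.22, percentile 0.0), and without Prg4 20 of the remaining 22 lay below the all-gene median, with a median of -0.38. Tenascin C (Tnc), a matrix glycoprotein, had an FPKM of 104 in the WT library and 59.6 in the Prg4KO library (log2 ratio -0.79). Thbs4, a thrombospondin of tendon and joint tissue, had 267 and 169 (-0.66), the Wnt-related secreted protein Dkk3 61.4 and 42.6 (-0.52), and the joint-forming growth factor Gdf5 6.72 and 4.45 (-0.50). Pcolce2, an enhancer of procollagen processing, went the other way with 75.9 and 124 (0.70), as did the transcription factor Erg with 9.78 and 12.6 (0.34). With the length and GC trend removed the list median was -0.45 (percentile 0.0). A different mix of collected cells cannot be told apart from a difference within superficial zone cells, since each library measured the RNA of all collected cells together. With 1 library per genotype, the spread between cultures is also unknown.

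In the tendon and ligament list, 9 of 9 measured members lay below the all-gene median, with a list median of -0.58 (-0.80 to -0.17, percentile 0.0). Of these, 1 (Col1a1) was past the limits. The list also holds Tpp1, a lysosomal peptidase gene that does not mark tendon, at an FPKM of 15.3 in the WT library and 14.9 in the Prg4KO library. Of the 9 members, 4 also stand in another list (Col1a1, Fmod, Thbs4 and Egr1). The other 5, Tpp1 among them, lay nearer to the rest, with Mkx in the middle at -0.31 relative to all genes. Fibromodulin (Fmod), a proteoglycan that organises collagen fibrils, had an FPKM of 3628 in the WT library and 2285 in the Prg4KO library (log2 ratio -0.67), and Scx, the tendon transcription factor scleraxis, had 513 and 360 counts (-0.47). Tnmd, a tendon membrane protein, had an FPKM of 321 and 314 (-0.03), with a count ratio of 0.980 (0.951 to 1.01). The synovial fibroblast list had a median of -0.20 over 9 members (percentile 4.04), with Pdpn at 54.1 and 47.5 and Hbegf at 64.6 and 75.6. After the trend was removed the medians were -0.53 for tendon and ligament (percentile 0.0) and -0.22 for synovial fibroblast (0.99).

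The chondrocyte genes did not share this direction. In the chondrocyte matrix list, 18 of 24 members lay above the all-gene median, and the list median was 0.13 (0.03 to 0.48), at the 89.6th percentile of random lists. Besides Epyc and Matn3, which passed the limits, the cartilage linker Hapln1 had an FPKM of 268 in the WT library and 452 in the Prg4KO library (log2 ratio 0.75), Matn1 387 and 643 (0.73), and the type IX collagen gene Col9a1 709 and 1115 (0.65). Col2a1 had a log2 ratio of 0.11, which lay at -0.03 relative to all genes. Sox9, the chondrocyte transcription factor, had 150 and 168 (0.16), or 0.03 relative to all genes. Acan, which encodes aggrecan, had 527 and 436 (-0.28). With the length and GC trend removed, the list median was 0.30 and lay above all random lists, so its place among them depends on that correction.

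Most genes of hypertrophic chondrocytes lay above the all-gene median, and Panx3 and Spp1 passed the limits. Relative to all genes Spp1 had a log2 ratio of 0.95, below the limit, and Panx3 had 1.10. The hypertrophic list had 12 of 15 members above the all-gene median, with a median of 0.18 (0.02 to 0.62, percentile 97.1), and of 0.29 after trend removal, above all random lists. Beside Panx3 and Spp1, Pth1r, the receptor for parathyroid hormone-related protein, had an FPKM of 53.7 in the WT library and 91.2 in the Prg4KO library (log2 ratio 0.75). Col10a1, the collagen of hypertrophic cartilage, had 241 and 301 (0.32), and Mmp13, a collagenase, had 56.5 and 76.6 (0.43). The osteoblast list had a median of 0.32 (-1.17 to 1.33, percentile 99.5, and 0.31 after trend removal) over 8 members, of which 6 stand in other lists. Of the 8 members, 6 lay above the all-gene median. Ibsp, encoding bone sialoprotein, had 6.10 and 12.2 (0.90), while Col1a1 in the same list was lower. No member of the osteoblast list was past the upper limit, but Ptprv and Panx3, outside this list, were. Bglap, encoding osteocalcin, had only 3.98 and 28.3 counts (ratio 7.07, 2.47 to 27.8), and its near-identical neighbour Bglap2 had 7.09 and 6.77.

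**Figure D2:**
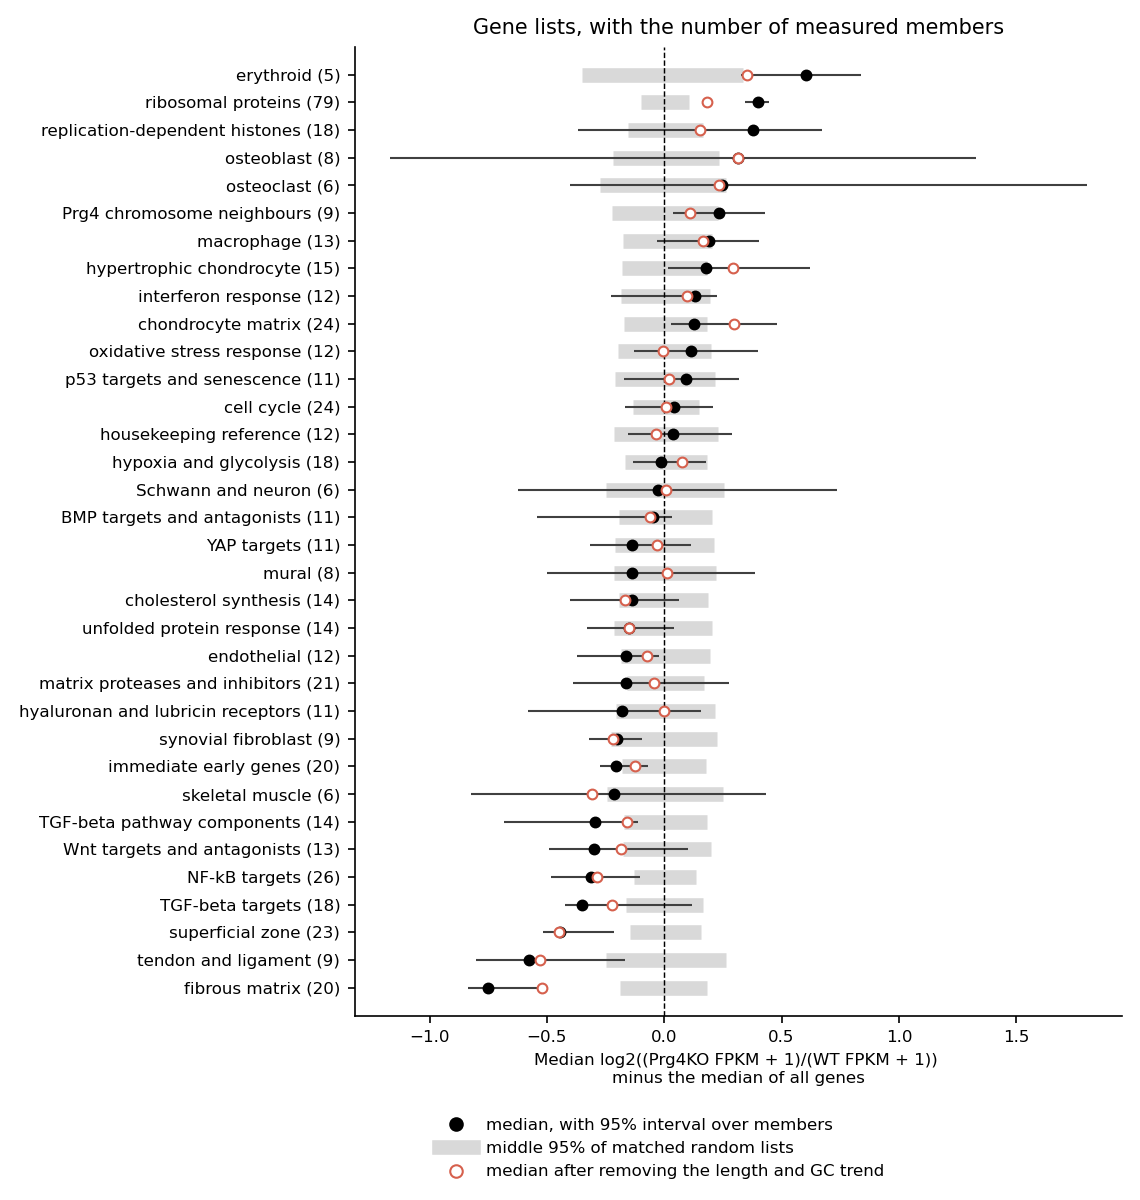
Median log2 ratio of each gene list minus the median of all genes (horizontal axis), with the number of measured members beside each name. Black points and lines give the median and its 95% interval over members, grey bars the middle 95% of matched random lists, and open circles the median after removing the length and GC trend; the fibrous matrix list lies lowest at -0.75.

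Lubricin has been studied as a restraint on NF-kB signalling and matrix breakdown, and the lists for these questions gave mixed values. Genes induced by NF-kB had a median of -0.31 relative to all genes (-0.48 to -0.10), below all random lists (percentile 0.0), with 19 of 26 members below the all-gene median and 0 past the limits. Nfkbia, the inhibitor of NF-kB that NF-kB itself induces, had 3807 counts in the WT library and 3301 in the Prg4KO library (log2 ratio -0.19), and the adhesion molecule gene Icam1 had an FPKM of 93.7 and 69.7 (-0.42). The chemokine gene Cxcl2 had 29.0 and 17.8 (-0.67). Ptgs2, which encodes the inducible cyclooxygenase and neighbours Prg4, had 8.68 and 13.3 (0.56), and Il1b had 0.73 and 2.21 (0.89). The transcription factor genes Nfkb1 (27.1 and 27.6, log2 ratio 0.03) and Rela (81.4 and 67.4, -0.27) lay below the all-gene median. After trend removal the list median was -0.29 (percentile 0.0).

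Among matrix proteases and their inhibitors, 1 of 21 measured members passed the limits, and this was Mmp9. The list median was -0.16 relative to all genes (-0.39 to 0.27, percentile 2.31). In absolute terms, the median log2 ratio of -0.03 and the mean of 0.13 differed in sign, and after trend removal the median was 0.09 (percentile 25.6). The gelatinase gene Mmp2 had an FPKM of 521 in the WT library and 396 in the Prg4KO library (log2 ratio -0.40), and Mmp14, its membrane-bound activator, had 211 and 158 (-0.42). The inhibitor genes differed, with Timp1 at 305 and 535 (0.81) and Timp2 at 404 and 302 (-0.42). The aggrecanase genes Adamts4 (5.99 and 5.56) and Adamts5 (1.81 and 1.56) had log2 ratios of -0.09 and -0.13.

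Transcripts of the TGF-beta pathway lay below the all-gene median as groups, with none past the limits. All 14 pathway components lay below the all-gene median, with a list median of -0.30 (-0.69 to -0.11, percentile 0.12, and -0.16 at percentile 1.61 after trend removal). Tgfb1 had an FPKM of 117 in the WT library and 104 in the Prg4KO library (log2 ratio -0.18). The latent TGF-beta binding protein genes had lower ratios, with Ltbp3 at 110 and 72.5 (-0.60) and Ltbp4 at 70.0 and 38.0 (-0.86). TGF-beta target genes had a median of -0.35 (-0.42 to 0.12, percentile 0.0, and -0.23 at percentile 0.13 after trend removal). Members lay on both sides: Ctgf, a matricellular growth factor, had 404 and 525 (0.38), Tgfbi 384 and 428 (0.15) and smooth muscle actin (Acta2) 33.0 and 21.9 (-0.57).

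Among the surface receptors that lubricin and hyaluronan bind, Cd44 and Tlr2 lay below the all-gene median and none passed the limits. Cd44 had an FPKM of 58.3 in the WT library and 50.4 in the Prg4KO library (log2 ratio -0.20), and Tlr2 had 46.1 and 33.5 (-0.45). Tlr4 was low in both at 0.66 and 0.71 from 114 and 122 counts, with a count ratio of 1.08 (0.831 to 1.41), so no difference was detectable at this depth. The list of 11 measured receptors and hyaluronan enzymes had a median of -0.18 (-0.58 to 0.16, percentile 4.01), and lay at the 39.7th percentile after trend removal.

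Of the other signalling lists, the Wnt list lay below the range of random lists. Wnt targets and antagonists had a median of -0.30 (-0.49 to 0.10, percentile 0.05, and -0.18 at percentile 0.69 after trend removal), with the antagonists Wif1 at an FPKM of 280 in the WT library and 249 in the Prg4KO library and Sfrp2 at 33.8 and 26.2. Immediate early genes, which respond within minutes to handling, had a median of -0.21 (-0.27 to -0.07, percentile 1.21), but of -0.12 at percentile 11.2 after trend removal, with Egr1 at 728 and 535 and Zfp36 at 425 and 378. BMP targets and antagonists (-0.05, percentile 30.2, and -0.06 after trend removal; Id1 at 88.5 and 99.4, Id3 at 108 and 115) and YAP targets (-0.14, percentile 9.69, and -0.03; Cyr61 at 715 and 719) stayed within the range of random lists.

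Markers of macrophages, osteoclasts and vessels were present in both libraries, as were those of red blood cells, with the globin gene Hba-a1 at an FPKM of 725 in the WT library and 1233 in the Prg4KO library. The macrophage list had a median of 0.19 (-0.03 to 0.40, percentile 96.5, and 0.17 after trend removal), with Cd68 at an FPKM of 21.1 in the WT library and 25.6 in the Prg4KO library and C1qa at 18.9 and 23.2. The osteoclast list had a median of 0.25 (-0.40 to 1.80, percentile 96.7, and 0.23 at percentile 98.5 after trend removal) over 6 members, 3 above and 3 below the all-gene median. Of these, Mmp9 and Acp5 passed the limits. The osteoclast protease gene Ctsk had 140 and 143 (log2 ratio 0.03), and Nfatc1 had 48.6 and 40.2 (-0.27). Endothelial genes had a median of -0.16 (percentile 4.09, and -0.07 after trend removal; Pecam1 26.6 and 25.7, Plvap 76.4 and 59.8), mural cell genes -0.14 (9.74, and 0.01; Cspg4 74.6 and 63.1, Pdgfrb 33.1 and 27.0) and skeletal muscle genes -0.22 (4.05, and -0.31 at percentile 0.23; Tnni2 9.24 and 8.31, Des 6.43 and 7.01). Schwann and neuron genes had a median of -0.03 (percentile 39.3, and 0.01 after trend removal), with S100b, which chondrocytes also express, at 35.4 and 65.5 and Tubb3 at 4.79 and 3.12.

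Lists with fewer than 5 measured members gave no median. Adipocyte genes had 4 measured members (Fabp4 15.5 and 26.6 FPKM in the WT and Prg4KO libraries, Cebpa 7.44 and 6.57), neutrophil and mast cell genes 4 (Mcpt4 3.25 and 2.26, Cma1 2.03 and 1.66), keratinocyte genes 1 (Epcam 3.67 and 5.94; Krt10 below the limit at 0.83 and 0.53) and lymphocyte genes 1 (Cd79a 1.23 and 0.68; Cd4 below it at 0.19 and 0.38). Sex-linked genes had 3. Of the 13 mitochondrially encoded genes, 0 had listed values.

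Stress, growth and metabolic lists lay within the range of random lists, also after trend removal, whose medians stand last in each bracket. Cell cycle genes had a median of 0.04 relative to all genes (percentile 67.8; Pcna 105 and 118 FPKM in the WT and Prg4KO libraries, Ube2c 34.4 and 38.6; 0.01), p53 targets and senescence genes 0.09 (77.6; Cdkn1a 369 and 357, Phlda3 46.5 and 48.0; 0.02) and hypoxia and glycolysis genes -0.01 (40.5; Eno1 476 and 591; 0.07). Cell cycle members lay on both sides, 14 above and 10 below the all-gene median, such as Cenpa at 9.38 and 18.15 and Mcm6 at 29.6 and 15.57. The unfolded protein response list had a median of -0.15 (8.49; Hspa5 389 and 379, Atf4 616 and 664; -0.15), cholesterol synthesis -0.14 (8.38; Fdps 154 and 168, Msmo1 135 and 128; -0.17) and interferon response 0.13 (90.1; Bst2 8.45 and 12.9, Cxcl10 12.1 and 9.75; 0.10). Oxidative stress genes had a median of 0.12 (85.3; -0.005), with Hmox1, the haem-degrading enzyme, at 195 and 371 (log2 ratio 0.92) and Prdx1 at 177 and 239 (0.43). Housekeeping reference genes had a median of 0.04 (58.7; -0.04), with Gapdh at 1577 and 1555 and Ppia at 1084 and 1380.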

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

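The tests on the row register were chosen after the deposited values had been seen. The tests on the fibrous matrix genes and on Mmp9 and Acp5 were set before their own results were computed, but after the genes with extreme ratios had been seen.

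The deposited Prg4KO columns hold 254 values beside no gene name, and 1 Prg4KO row with an FPKM of 5 or more was left without a gene at a pairing probability of 0.95. They drew attention because the deposited table gives the 254 values no gene. In the deposited rows the Prg4KO values were nearly uncorrelated with the WT values (r = 0.0851 across genes). A difference between the genotypes or a failed library would leave the correlation low after re-pairing or the quantiles of the libraries far apart. Neither was seen: the correlation over re-paired rows was 0.981, and quantiles from the 5th to the 95th percentile differed by at most 1.095-fold. The same value of 0.981, from a model that uses order, effective length and the nearness of a count to 0 but does not compare levels, is consistent with Prg4KO values entered out of register with the gene names, as would happen if rows absent from the WT library had been pasted beside its gene column. No source used here states how the table was put together.

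The lower fibrous matrix genes in the Prg4KO library were weighed against a technical trend and a difference in cell mixture. A trend with transcript length and GC content, fitted on all other genes, moved the list median from -0.75 (-0.84 to -0.52) to -0.53 (-0.62 to -0.36), so it argues against that trend as the whole source. A smaller share of tendon, ligament or synovial fibroblast cells could lower these genes, although the protocol removed those tissues. Members of the tendon and synovial lists outside the fibrous matrix list had a median of -0.31 (-0.56 to -0.17, 17 genes) relative to all genes. These genes include Tpp1, which does not mark tendon. The level set in advance was -0.38. The interval spans that level, so the mixture and a difference within cells cannot be told apart. Genotype stays open and was not tested, since 1 library per genotype carries no spread.

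The higher Mmp9 and Acp5 in the Prg4KO library may come from more osteoclasts in that culture. The osteoclast genes Ocstamp, Oscar, Atp6v0d2 and Calcr (Dcstamp had no paired value) summed to 63 counts in the WT library and 125 in the Prg4KO library, a ratio of 2.005 (1.47 to 2.76); Atp6v0d2 carried most of the difference with 27 and 74, while Calcr had 4 and 2. The ratio narrowly met the level of 2 set in advance, but the interval spans it, and the demand that the interval clear it was made only after the value was seen. The Mmp9 ratio of 4.03 (3.76 to 4.33) lay above that interval but inside that of Atp6v0d2 alone (2.77, 1.76 to 4.48). These counts do not separate osteoclasts from other cells, so they cannot decide how much of the Mmp9 ratio more osteoclasts would cover. Ctsk had an FPKM of 140 and 143 and Nfatc1 of 48.6 and 40.2, with the same limit. A rise in macrophages large enough to cover both ratios is argued against by the macrophage list. Its median of 0.19 had an upper end of 0.40, below the 0.8 set in advance. With 10 of its 13 measured members above the all-gene median, a smaller rise in such cells stays open. Removing the length and GC trend left the smaller of the log2 ratios of Mmp9 and Acp5 at 1.57. An effect of genotype within cells was not tested.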

How the results depend on the processing

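The pairing alternatives and the removal of the length and GC trend were chosen after seeing the data, and the others before. No paired analysis was possible because each genotype has 1 library, the shared number 1 is only a name, and no test was made. Leaving out a replicate was not possible either. Prg4 stayed far lower under all alternatives run, with log2 ratios of -11.53 at a pseudocount of 0.1, -6.87 at 5 and -13.04 with TMM on counts, where the pseudocount sets the size. Genes higher and lower numbered 34 and 8 as reported, and 33 and 9 under the first pairing model, where 41 of the 42 were shared. The higher genes numbered 54 at a pseudocount of 0.1, 11 at 5, 22 rescaled to a common sum, 16 to a common median, 18 to a common upper quartile, 19 without the 20 most abundant genes, 18 with the trend removed, 465 at a limit of 1.5-fold and 1 at a limit of 2 on the log2 ratio. The lower genes numbered 3 at a pseudocount of 5, 19, 17, 13 and 22 under those rescalings in the same order, 25 with TMM, 5 with the trend removed, 112 at 1.5-fold and 1 at the limit of 2. A common sum, with or without the 20 genes, also changes what a pseudocount of 1 means. Rescaling shifted the all-gene median from 0.13 to between -0.04 and 0.02, and the lists with it. In the order common sum, median, upper quartile, sum without the 20 genes and TMM, the absolute medians were -0.76, -0.76, -0.73, -0.80 and -0.78 for fibrous matrix, -0.50, -0.40, -0.39, -0.55 and -0.56 for superficial zone (-0.60 as a mean, which Prg4 itself pulls down), -0.37, -0.34, -0.32, -0.40 and -0.37 for TGF-beta targets, and 0.12, 0.12, 0.14, 0.081 and 0.10 for chondrocyte matrix. With the sum without the 20 genes, NF-kB targets had -0.36 and hypertrophic genes 0.15. Signs turned for matrix proteases (0.094 with the trend removed, 0.13 as a mean) and immediate early genes (0.013 with the trend removed), and the cause was not tested. Of 510 alternatives over 34 lists, 3 turned the sign of a median outside the random range, and 45 left the interval of the main median. Depth limits genes such as Tlr4, whose interval of the ratio includes 1.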

Other observations

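The comparison by chromosome and the length deciles were chosen after the results were seen, and the gene lists before. Genes of ribosomal proteins and of red blood cells lay above the all-gene median as groups. Of 79 ribosomal protein genes, 76 lay above the all-gene median, with a list median of 0.40 relative to all genes (0.34 to 0.45, above all random lists) and of 0.18 after the length and GC trend was removed, still above all of them. Rps27a had an FPKM of 283 in the WT library and 601 in the Prg4KO library, and Rpl22l1 had 62.4 and 130. Short transcripts were higher in general, with a median log2 ratio of 0.33 in the lowest decile of length, up to 1032 bases, and -0.02 in the highest, from 5222 bases. These 2 medians are absolute, where the all-gene median was 0.13, while the list medians here are relative to it. Erythroid genes had a median of 0.60 (0.33 to 0.84, percentile 99.97, and 0.35 after trend removal) over 5 members, with the globin genes Hba-a1 at 725 and 1233 and Hbb-bs at 513 and 856, whose near-identical copies share reads. Replication-dependent histone genes had a median of 0.38 (-0.37 to 0.67, above all random lists, and 0.15 at percentile 98.6 after trend removal) with members on both sides, such as Hist1h2ap at 203 and 161 and Hist1h2bc at 73.7 and 129. The list was taken by symbol and also holds H1f0 and H1fx, which are replication-independent. The replication-dependent genes largely lack poly(A) tails and share sequence, so their values are uncertain.

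Of the Y-linked genes, Eif2s3y was past the limits, and Ddx3y, Uty and Kdm5d had more counts in the Prg4KO library without passing them. Eif2s3y had 96 counts in the WT library and 285 in the Prg4KO library, and Ddx3y had 380 and 821 (ratio per library total 2.18, 1.93 to 2.47). Uty had 68 and 121 counts (1.80, 1.33 to 2.46) and Kdm5d had 77 and 116 (1.52, 1.13 to 2.06). Ddx3y, Uty and Kdm5d were named after their values were seen. Xist had no listed value under that symbol, and the sex of the mice is not in the labels used here. A different share of male mice in the 2 libraries therefore cannot be told apart from genotype.

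Genes higher in the Prg4KO library were frequent on the chromosome that carries Prg4, an observation made after their positions were seen. Chromosome 1 held 393 of 7364 genes with a larger FPKM of at least 5 and a position, Prg4 left out, which is 5.34%. It held 6 of the 34 higher genes, which were Ptprv, Wdfy1, Elf3, Chil1, Nhej1 and Steap3, and 0 of the lower ones. Ptprv, Elf3 and Chil1 lay 15.3, 15.2 and 16.3 Mb from Prg4. Within 20 Mb of Prg4, 3 of 102 genes (2.94%) were past the limits, against 0.502% on other chromosomes. Windows of that size around other genes held as many or more in 7.18% of cases and at most 4. Such windows overlap, differ in gene number and include windows that hold Ptprv, Elf3 and Chil1. By chromosome, 1.53% of genes were past the limits on chromosome 1, and the next autosomes were 9 (1.21%) and 17 (1.09%). The fixed list of the genes next to Prg4 had 9 of 9 measured members above the all-gene median, with a median of 0.23 (0.04 to 0.43, percentile 97.8). After trend removal it was 0.11 (percentile 85.0), inside the range of random lists. Among these neighbours Ivns1abp had an FPKM of 39.4 in the WT library and 64.7 in the Prg4KO library and Rnf2 had 20.6 and 27.9.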
